A study of Homo sapiens with 18 samples.

How the data were processed

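Gene expression was measured on 18 cDNA arrays with 2 colours, each hybridised with RNA of PDGF-BB-treated AG01518 fibroblasts and RNA of cells starved for the same time. Per the labels, RNA of treated cells was labelled with Cy5 and RNA of starved cells with Cy3, and the dyes were exchanged in every second replicate experiment. The labels do not say which arrays these were. Per the labels, the arrays were of the Sanger Institute, LICR and CRUK design hver1.2.1, spot intensities were measured in QuantArray by its histogram method with background subtraction, and the ratios were normalized in GeneSpring 5.0 by lowess with the median ratio of each array set to 1. Per the labels, the authors called features with a mean ratio above 1.75 or below 0.571 and a t-test p under 0.05. Each time point had at least 4 hybridizations and at least 2 RNA batches, which are not assigned to arrays.

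The deposited values are log ratios, taken as log2 ratios of PDGF-BB over starved cells. The authors deposited them without stating the base of the logarithm or the sign convention. A base of 10 was set aside because the deposited extremes of -4.58 and 3.91 would then be implausible ratios, and a natural log remains possible. The direction was taken from the labels, which give starved cells as the first and PDGF-treated cells as the second channel of every sample. Of the immediate-early genes, NR4A1, EGR3 and JUNB, known to rise early after growth factor stimulation, had positive values at 1 h on all 4 arrays. For the 4 h arrays d and e it is not settled. There were 0 missing cells in 9928 features, the array medians lay between -0.031 and 0.0061, and no per-sample column was left unused. No spot intensities or flags were used here, so the signal over background behind each ratio is unknown. The SD of all log ratios of an array ran from 0.243 to 0.520, widest for 24 h arrays c and e.

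Features were named through the platform annotation provided with the values: 5963 had 1 gene symbol, 39 had several and 3926 had none. Of the former, 5958 matched the gene table by Entrez ID and 0 symbols needed updating. Log ratios of the features of a gene were averaged per array, which gave 3809 genes, 1709 of them with more than 1 feature. Features with several symbols or none were left out of the gene tests. Among 40 pairs of a named gene and a time with more than 1 feature, 1 had features of opposite sign (NR4A3 at 24 h, with feature means of -0.95 and 0.08).

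Each time point's mean log ratio was tested against 0 in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 18 arrays, 1 mean per time point and 1 spread per gene, with 14 residual and 5.56 prior degrees of freedom. Differences between neighbouring time points were contrasts of the same fit, and the whole course was tested with the moderated F test. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No normalization was added. In total 24 gene lists with 690 genes, 259 of them measured, were tested with camera at a preset correlation of 0.01 for lists with at least 5 measured genes, with an estimated correlation and fry as alternatives. The named genes were those past the threshold with 1 sign on all arrays of the time point, up to 8 rises and 8 falls by size. To these came up to 4 members per list by adjusted p, the 3 largest differences each way between time points, and 12 fixed genes where measured, some of which are not reported here. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. Other genes called for a list, and counts of 8 or fewer given by name, were named after their values were seen. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

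The fit was tested on simulated data made with the spread of the real genes, 5 data sets of 3809 genes. At 10 h it called 63.9% of genes changed by 0.5, 96.4% of those changed by 1 and 99.7% of those changed by 2. At 24 h it called 77.6%, 97.9% and 99.7%. False calls were 4.73% of calls at 10 h and 4.18% at 24 h. In 20 data sets with 1 list shifted by 0.4, camera called that list 20 times and made 5 other calls in total. The simulated genes were drawn independently of each other. These data sets therefore do not show how often camera errs where the genes of a list are correlated. The simulated noise of a gene also had the same spread on every array, with no effect of array, dye or batch. The shares of genes called and of false calls hold for that setting and may differ in the real data.

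Alternatives covered centring, scaling to equal spread and quantile normalization across arrays, features instead of genes, the median of a gene's features, robust eBayes, array quality weights, each time point alone, the replicate letter as a block, a dye term and a turned sign for letters b and d, stricter thresholds, the methods' t-test and leaving out each array in turn. Settings added after seeing the data were the 4 h arrays d and e left out or turned, the 24 h arrays c and e left out, the authors' ratio limits with natural logs, and a dye term read from an unnamed feature.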

Results

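The series followed the transcriptional response of human AG01518 fibroblasts, a cultured fibroblast strain, to platelet-derived growth factor BB (PDGF-BB), a mitogen for cells of mesenchymal origin. The cells were starved for 16 h in medium with 0.1% bovine serum albumin and then given PDGF-BB at 10 ng/ml for 1, 4, 10 or 24 h. Each of the 18 cDNA arrays carried RNA of stimulated cells and RNA of cells starved for the same time, so a log ratio of 0 means equal levels. There were 4 arrays at 1 h, 5 at 4 h, 4 at 10 h and 5 at 24 h. The deposited values are log ratios for 9928 features, of which 5963 carry a single gene symbol and give 3809 genes. The base of the logarithm is not stated and was taken as 2. Signs and limma's tests do not depend on the base, while every fold below and every count with the authors' ratio limits holds only for base 2 unless a natural log is named. The values hold no spot intensities, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision. The median standard error of a gene's mean log ratio was 0.121 for 4 arrays and 0.108 for 5. The labels say that at least 2 RNA batches were used per time point without saying which arrays share one, so the p-values measure the spread between arrays, part of which may be technical. The array files name no genome build, so genes are given by symbol alone.

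The first comparison asked which genes had responded after 1 h. In limma, 17 of 3809 genes rose at an adjusted p under 0.05 and 0 fell. The orphan nuclear receptor NR4A1 rose most, with a log ratio of 2.95 ± 0.09 (SD, n = 4), a 7.74-fold rise (adjusted p = 8.0e-14). DUSP1, a phosphatase that inactivates MAP kinases, rose by 2.65 ± 0.18 (SD, n = 4; adjusted p = 1.4e-07). The transcription factors EGR3 and JUNB rose by 2.12 ± 0.26 and 2.08 ± 0.32 (SD, n = 4). PTGS2, the inducible cyclooxygenase, rose by 2.01 ± 0.69, and the small GTPase RHOB by 1.59 ± 0.28 (SD, n = 4). DUSP5, a phosphatase for nuclear ERK, rose by 1.32 ± 0.05, and the transcriptional repressor KLF10 by 1.28 ± 0.32 (SD, n = 4). All these genes were above 0 on 4 of 4 arrays.

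Among 18 measured genes of the immediate-early list, not all of which are transcription factors, 6 rose at 1 h over all genes tested. When adjusted over the list alone 11 rose, and all 18 had a mean above 0. The 6 were NR4A1, EGR3, JUNB, KLF10, ZFP36L1 (0.78) and FOSL1 (0.68). The list stood above the other genes in limma's camera test (adjusted p = 3.2e-51, and adjusted p = 2.8e-09 with an estimated correlation). Of 11 receptor tyrosine kinase feedback genes, 4 rose, or 6 when adjusted over the list alone: DUSP1, DUSP5, DUSP4 (0.89 ± 0.61, SD, n = 4) and SPRY2 (0.74 ± 0.26, SD, n = 4), a Sprouty inhibitor of receptor signalling. This list also passed (adjusted p = 6.5e-18, and adjusted p = 0.0034 with an estimated correlation). The interferon response list passed (adjusted p = 0.040) with IRF1 alone of its 11 members rising, by 1.17 ± 0.37 (SD, n = 4), and did not pass with an estimated correlation (adjusted p = 0.36). MYC had a log ratio of 0.43 ± 0.13 (SD, n = 4) and did not pass (adjusted p = 1.00). The immediate-early genes FOS and EGR1, set to be reported in any case, have no measured feature with a single symbol. Leaving out array a or array c took the count at 1 h from 17 to 11.

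**Figure D1:**
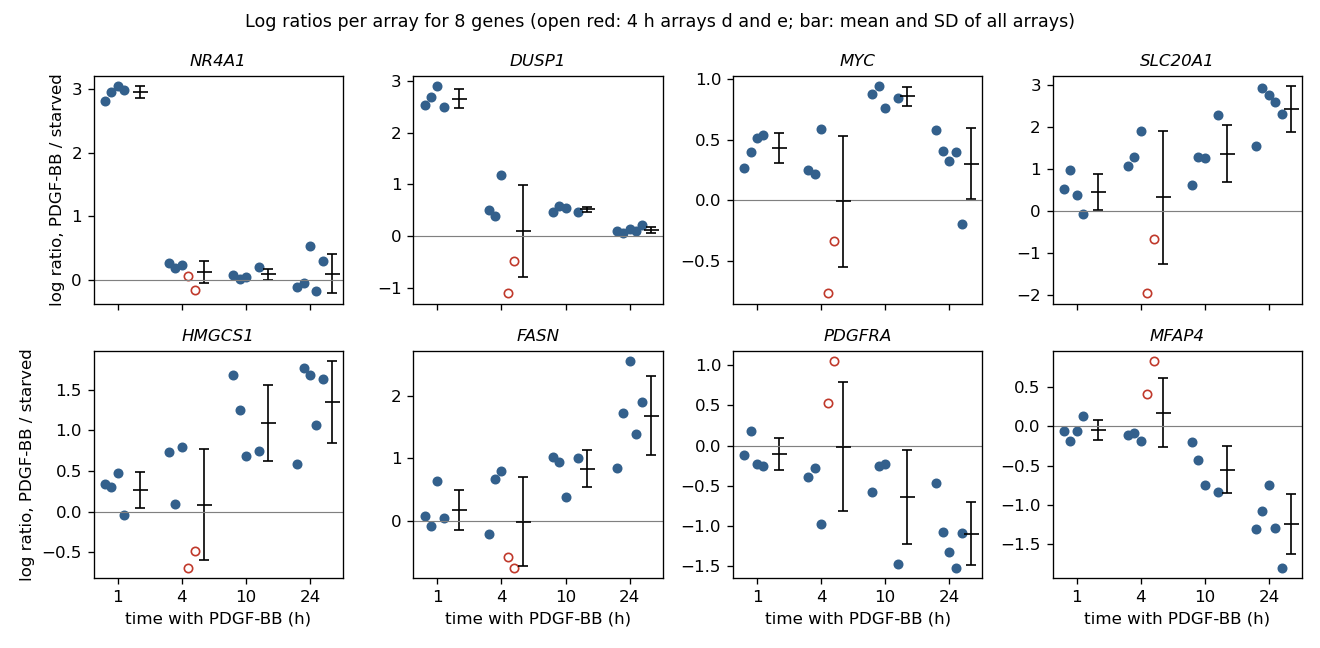
Log ratios of PDGF-BB over starved cells (y axis, base taken as 2) against time in h (x axis) for 8 genes, each point being 1 array and each bar the mean and SD of all arrays of that time. NR4A1 has its highest mean, 2.95, at 1 h, SLC20A1 and FASN reach 2.44 and 1.68 at 24 h, and the open red points (4 h arrays d and e) lie on the other side of 0 from arrays a, b and c for most of these genes.

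At 4 h the arrays did not run the same way. Over all features, arrays d and e correlated with arrays a, b and c at r = -0.53 to -0.09, while a, b and c correlated with each other at 0.19 to 0.52. Arrays d and e correlated with each other at -0.016 over all features. Pairs below 0 were also found within other time points, down to -0.13 at 1 h and -0.028 at 24 h. Over 151 genes called from the 24 h arrays alone, d and e correlated with a, b and c at -0.84 to -0.53, and d with e at 0.52. These correlations are across genes, which are not independent replicates. The labels give PDGF-BB as the second channel of every sample and say that dyes were swapped in every second replicate, without naming the arrays. The direction of the 4 h arrays is therefore not settled, and 4 h counts, named genes and lists are given as deposited, without d and e, and with the sign of d and e turned. The latter settings were chosen after seeing the data.

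As deposited, limma called 0 genes at 4 h, with 45 genes at an unadjusted p under 0.05. The methods' t-test called 0 genes with the authors' ratio limits and 0 after Benjamini-Hochberg adjustment. Without d and e, 19 genes rose and 4 fell. With d and e turned, 77 rose and 38 fell, and these 115 included all 23 of the former. Both settings hold arrays a, b and c, and d and e were turned because they ran against these. Agreement between the settings is therefore partly built in and is no separate support for a gene or list. On arrays a, b and c, the phosphate transporter SLC20A1 rose by 1.42 ± 0.43 (SD, n = 3; adjusted p = 0.016). The splicing factor SRSF7 rose by 0.98 ± 0.03, the interferon-inducible GTPase GBP1 by 0.96 ± 0.11 and the kinase MAP2K3 by 0.81 ± 0.13 (SD, n = 3). HBEGF, an EGF receptor ligand, rose by 0.80 ± 0.46, and the interleukin 1 receptor gene IL1R1 by 0.72 ± 0.21 (SD, n = 3). CYP1B1, a cytochrome P450, fell by 0.92 on the log scale, with an SD of 0.59 (n = 3), and the zinc finger gene TSHZ1 by 0.57, with an SD of 0.23 (n = 3). With d and e turned, SLC20A1 was at 1.38, SRSF7 at 0.96, GBP1 at 0.97, MAP2K3 at 0.75, HBEGF at 0.79, IL1R1 at 0.59, CYP1B1 at -0.60 and TSHZ1 at -0.53, each past the threshold. As deposited these genes were, in that order, at 0.33, 0.22, 0.18, 0.22, 0.17, 0.27, -0.50 and -0.15, none past the threshold (adjusted p = 1.00 for each).

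On arrays a, b and c, 4 of 11 receptor tyrosine kinase feedback genes rose at 4 h: DUSP5 (0.93), SOCS2 (0.71), DUSP1 (0.69) and RGS2 (0.61). The list passed camera (adjusted p = 1.7e-08, and adjusted p = 0.0010 with an estimated correlation). Of 11 cell cycle inhibitors and FOXO targets, TXNIP (-0.86 ± 0.26) and the cyclin gene CCNG2 (-0.83 ± 0.42) fell, and GADD45A, a stress-induced growth arrest gene, rose by 0.82 ± 0.45 (SD, n = 3). This list was lower than other genes (adjusted p = 0.0056, and adjusted p = 0.047 with an estimated correlation). The growth factor list was higher (adjusted p = 0.0046, and adjusted p = 0.047 with an estimated correlation) with HBEGF the 1 of 13 genes called. The nucleolus list, with DKC1 at 0.55, and the interferon list, with GBP1, passed too and did not with an estimated correlation (adjusted p = 0.17 and adjusted p = 0.099). With d and e turned, DUSP5 was at 0.95, SOCS2 at 0.61, DUSP1 at 0.73, RGS2 at 0.55, TXNIP at -0.93, CCNG2 at -0.79, GADD45A at 0.97 and DKC1 at 0.53, each past the threshold. As deposited these genes were, in that order, at 0.16, 0.24, 0.098, 0.18, -0.098, -0.20, 0.011 and 0.12, none past the threshold (adjusted p = 1.00 for each). With d and e turned, the feedback list (adjusted p = 3.2e-09, and adjusted p = 0.00084 with an estimated correlation) and the growth factor list (adjusted p = 0.0057, and adjusted p = 0.040 with an estimated correlation) passed both ways. The inhibitor list then passed (adjusted p = 0.011) and did not with an estimated correlation (adjusted p = 0.073). So did the nucleolus (adjusted p = 0.0080, and adjusted p = 0.18 with an estimated correlation) and interferon lists (adjusted p = 0.020, and adjusted p = 0.18 with an estimated correlation). As deposited 0 of 24 lists passed, and these lists, in that order, had adjusted p = 0.42, 0.42, 0.29, 0.22 and 0.22.

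**Figure D2:**
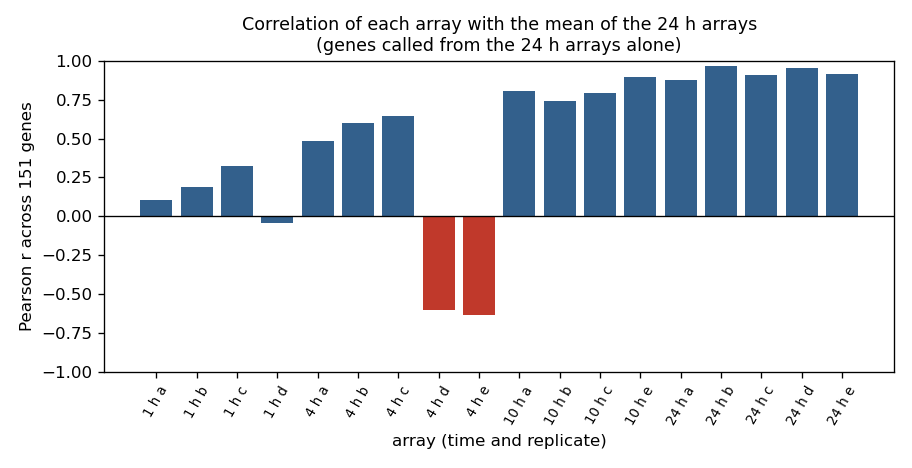
Pearson correlation across 151 genes (y axis) of each array (x axis) with the mean of the 24 h arrays, which for a 24 h array leaves that array out. The 10 h arrays lie at 0.74 to 0.90 and the 4 h arrays a, b and c at 0.48 to 0.65, while the 4 h arrays d and e (red) lie at -0.60 and -0.63.

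At 10 h, 24 genes rose and 5 fell as deposited. The tubulin genes TUBA1A, TUBA8 and TUBB2A rose by 1.14 ± 0.18, 1.11 ± 0.10 and 0.87 ± 0.16 (SD, n = 4). Tubulin genes are close in sequence, and a cDNA feature for one can bind transcripts of others, so the family member is uncertain. HMGCS1, the synthase that makes HMG-CoA for cholesterol synthesis, rose by 1.09 ± 0.47 (SD, n = 4; adjusted p = 0.026), a 2.13-fold rise. ACAT2, which makes acetoacetyl-CoA, rose by 0.76 ± 0.29 (SD, n = 4). The splicing factor SRSF3 rose by 1.00 ± 0.25, the transcription factor MYC by 0.86 ± 0.08 and the calcium sensor HPCAL1 by 0.85 ± 0.18 (SD, n = 4). The 5 genes that fell were ID2B (-0.82 ± 0.42), the RNA helicase gene DDX17 (-0.71 ± 0.17), LINC02249 (-0.68 ± 0.08), CSRP2 (-0.52 ± 0.27) and the growth factor receptor gene IGF1R (-0.51 ± 0.25; SD, n = 4 each). ID2B is a pseudogene close in sequence to ID2, so its feature may also bind ID2 transcripts.

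Of 8 measured genes of cholesterol synthesis and uptake, HMGCS1 and ACAT2 rose at 10 h, or 4 genes when adjusted over the list alone, and 7 had a mean above 0. The list passed camera (adjusted p = 0.0010) and did not with an estimated correlation (adjusted p = 0.17). In all, 9 lists passed at 10 h and 0 did with an estimated correlation. Higher than other genes were also the nucleolus (estimated-correlation adjusted p = 0.20), contractile cytoskeleton (adjusted p = 0.28), amino acid response (adjusted p = 0.17), endoplasmic reticulum chaperone (adjusted p = 0.20), respiratory chain (adjusted p = 0.28) and receptor tyrosine kinase feedback lists (adjusted p = 0.41). Lower were the matrix structure (adjusted p = 0.28) and growth factor receptor lists (adjusted p = 0.17). Members called were MTHFD2, a mitochondrial folate enzyme, at 0.42 ± 0.15 (SD, n = 4) for the amino acid list and IGF1R for the receptor list. PDGFRB, a receptor for PDGF-BB, had -0.61 ± 0.25 (SD, n = 4) and did not pass (adjusted p = 0.088).

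The count at 10 h moved with the arrays in the fit. All time points share 1 spread per gene, so the 4 h arrays bear on the 10 h calls without changing the 10 h means. Without the 4 h arrays d and e, 103 genes rose and 32 fell, and with these turned 120 rose and 45 fell. All 29 genes were called in both settings. Among the genes added were SLC20A1 (1.37 ± 0.68), HBEGF (1.01 ± 0.28), FASN (0.84 ± 0.30), AURKA (0.82 ± 0.32) and DUSP5 (0.82 ± 0.25; SD, n = 4 each). Leaving out 10 h array a, b, c or e left 16, 5, 2 or 5 genes, and TUBA8, HMGCS1, SRSF3, LINC02249 and CSRP2 lost their calls whichever of the 4 was left out.

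**Figure D3:**
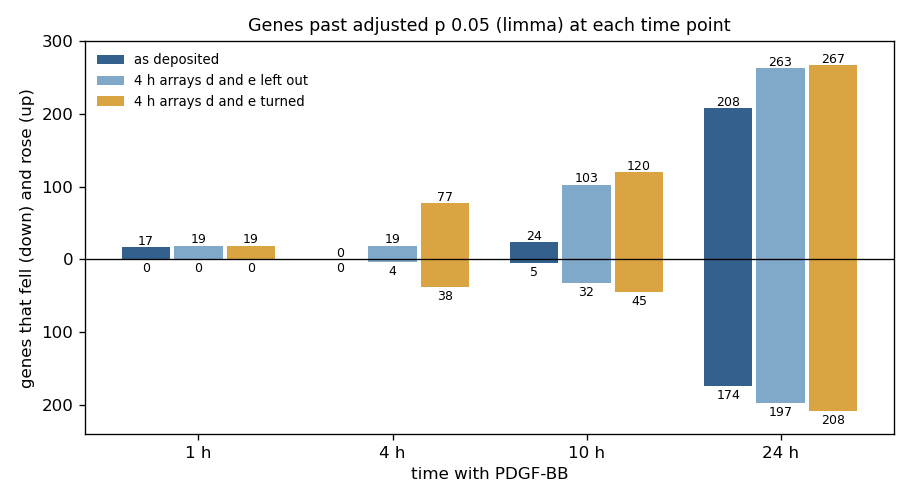
Number of genes (y axis) that rose (above 0) or fell (below 0) at each time point (x axis) at an adjusted p under 0.05 in limma. Bars stand for the values as deposited, without the 4 h arrays d and e, and with their sign turned: at 24 h 208, 263 and 267 genes rose.

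At 24 h, 208 genes rose and 174 fell. With each time point fitted alone, 84 rose and 67 fell at 24 h, while 138 rose and 81 fell at 10 h. Which of these times has more calls therefore depends on the spread used. In the fit of all arrays, SLC20A1 rose most at 24 h, by 2.44 ± 0.54 (SD, n = 5), a 5.41-fold rise (adjusted p = 0.00020). TUBA1A rose by 2.25 ± 0.48, TUBA8 by 2.19 ± 0.82 and TUBB2A by 1.54 ± 0.40 (SD, n = 5). PLAU, the urokinase plasminogen activator, rose by 1.81 ± 0.36, and the aminopeptidase gene ANPEP by 1.49 ± 0.56 (SD, n = 5). FASN, fatty acid synthase, rose by 1.68 ± 0.63, a 3.21-fold rise (SD, n = 5; adjusted p = 2.7e-05). The largest falls were those of MFAP4, a microfibril-associated matrix protein (-1.24 ± 0.38), and PDGFRA, the PDGF alpha receptor (-1.10 ± 0.39; SD, n = 5 each). The lipid phosphatase gene PLPP3 (-1.05 ± 0.27), the cathepsin gene CTSF (-1.02 ± 0.19), the elastic fibre gene FBLN5 (-1.002 ± 0.28) and NREP (-0.99 ± 0.39) followed (SD, n = 5 each). The chemokine receptor gene ACKR3 (-0.98 ± 0.44) and PSG11 (-0.99 ± 0.46; SD, n = 5 each) also fell. PSG11 belongs to a family of near-identical genes, so its features may bind other members.

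Of 8 measured genes of cholesterol synthesis and uptake, 5 rose at 24 h, or 6 when adjusted over the list alone, and all 8 had a mean above 0, with a list median of 0.71. They were ACAT2 (1.45 ± 0.29), HMGCS1 (1.35 ± 0.50), DHCR7, which makes the last step to cholesterol (0.98 ± 0.44), MSMO1 (0.90 ± 0.24) and INSIG1, a sterol-responsive regulator of SREBP (0.39 ± 0.27; SD, n = 5 each). The list passed camera (adjusted p = 3.1e-07, and adjusted p = 0.029 with an estimated correlation), the 1 list of 24 at this time that passed both ways. Of 7 genes of fatty acid synthesis, 3 rose, or 4 when adjusted over the list alone: FASN, the citrate carrier gene SLC25A1 (0.64 ± 0.39) and ACSL4 (0.49 ± 0.59; SD, n = 5). ACSL4 was above 0 on 3 of 5 arrays. This list passed (adjusted p = 0.0068) and did not with an estimated correlation (adjusted p = 0.088). Both lists were drawn up knowing that the study went on to lipid synthesis, so they are not independent evidence of its direction. SCD has no measured feature with a single symbol.

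Of 11 cell cycle inhibitors and FOXO targets, IGF1R (-0.67 ± 0.09) and BTG1, an antiproliferative gene (-0.40 ± 0.27), fell at 24 h (SD, n = 5 each), 8 fell when adjusted over the list alone, and 10 had a mean below 0. The list passed (adjusted p = 0.00028) and did not with an estimated correlation (adjusted p = 0.067). Without the 4 h arrays d and e, 6 fell and the list passed both ways (adjusted p = 0.012 with an estimated correlation). Of 10 receptors, PDGFRA and IGF1R fell and 9 had a mean below 0 (adjusted p = 0.012, and adjusted p = 0.094 with an estimated correlation). PDGFRB was at -0.28 ± 0.51 (SD, n = 5; adjusted p = 0.28). Of 11 ribosomal proteins, RPL13A (-0.38), RPL10 (-0.38), RPL13 (-0.36) and RPL11 (-0.33) fell, and 7 did when adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.070 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes that cDNA features may not tell apart.

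Matrix genes moved both ways at 24 h. Of 16 matrix structure genes, MFAP4, FBLN5, FBLN2 (-0.92 ± 0.48), LUM (-0.86 ± 0.37) and COL5A2 (-0.45) fell, while COL6A3 (0.64) and PLOD2 (0.45), a collagen lysyl hydroxylase, rose. The list was lower than other genes (adjusted p = 0.021) and not with an estimated correlation (adjusted p = 0.27). Of 16 matrix proteases and inhibitors, PLAU, its receptor gene PLAUR (0.79 ± 0.37), TIMP1 (0.56 ± 0.18) and ADAM9 (0.32) rose, and CTSK (-0.78 ± 0.25) and MMP2 (-0.47) fell, and the list did not pass (adjusted p = 0.21). In the contractile cytoskeleton list, 5 of 11 rose, among them ZYX (0.73 ± 0.53) and VCL (0.69 ± 0.28), proteins of focal adhesions, and LMOD1 fell (-0.49 ± 0.13; SD, n = 5 each). This list passed (adjusted p = 0.011) and did not with an estimated correlation (adjusted p = 0.27). PKM (1.06 ± 0.41) and ALDOA (0.48 ± 0.42) rose among 6 glycolysis genes (SD, n = 5; adjusted p = 0.010, and adjusted p = 0.094 with an estimated correlation). RRP9 (0.36 ± 0.04; SD, n = 5) rose among 6 nucleolus genes (adjusted p = 0.011, and adjusted p = 0.27 with an estimated correlation), and 3 did without the 4 h arrays d and e.

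Cell division genes did not move as lists at 24 h. Of 17 genes of the G1/S transition and DNA replication, 0 were called, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.61). Of 20 mitotic genes, the kinase gene AURKA rose by 1.03 ± 0.48 and HMGB2 fell (-0.36 ± 0.18; SD, n = 5; list adjusted p = 0.20). Markers of other cell types were among the calls at this time. KRT15, a keratin of basal keratinocytes, rose by 0.96 ± 0.48, and ENG, an endothelial marker that fibroblasts also express, by 0.61 ± 0.34 (SD, n = 5). They were the 1 of 6 keratinocyte and 1 of 9 endothelial markers called, 0 of 12 leukocyte and 0 of 9 melanocyte markers were, and none of the 4 lists passed (adjusted p = 0.57, 0.46, 0.61 and 0.34). Leaving out 24 h array b took the count of 382 genes to 233, and scaling all arrays to an equal spread took it to 134.

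**Figure D4:**
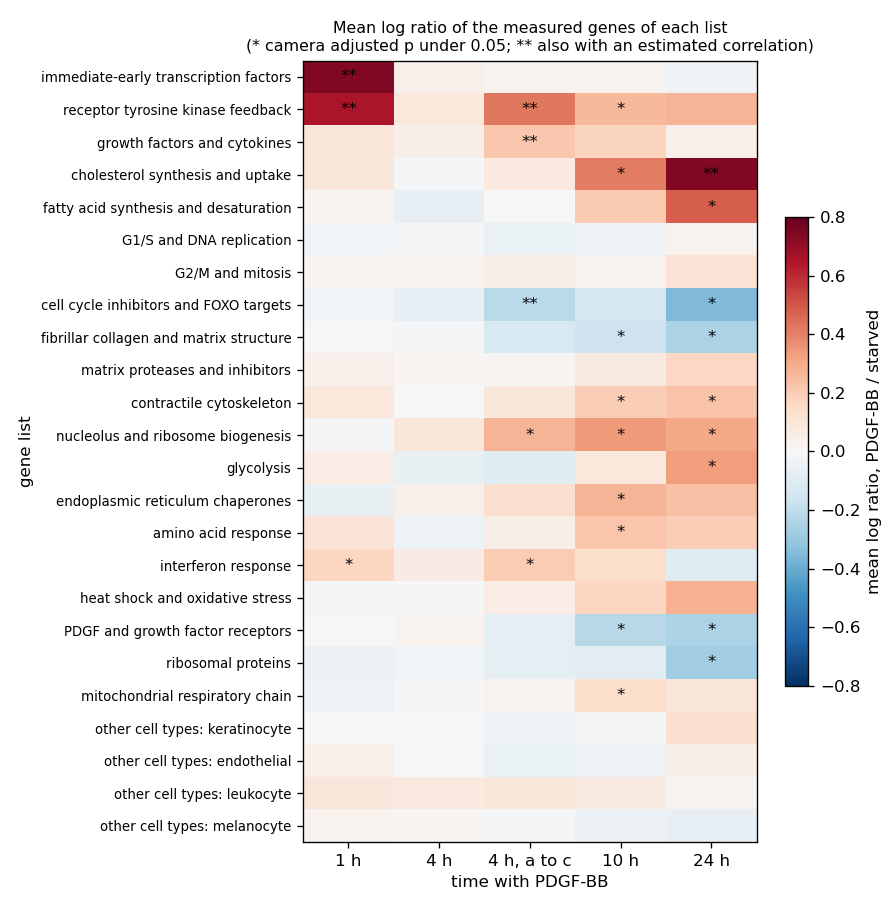
Mean log ratio of the measured genes (colour, base taken as 2) of 24 gene lists (rows) at each time point (columns), with 4 h shown for all arrays and for arrays a, b and c. Stars mark camera adjusted p under 0.05 (2 stars: also with an estimated correlation): the immediate-early list has 2 stars at 1 h and the cholesterol list has 2 stars at 24 h.

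The design also asks whether the response itself differed between neighbouring time points. Between 1 h and 4 h, 8 genes differed, all lower at 4 h: NR4A1 (difference -2.83 ± 0.14, SE), DUSP1 (-2.55 ± 0.29), EGR3 (-2.15 ± 0.14), JUNB (-1.87 ± 0.23), RHOB (-1.754 ± 0.23), NFIL3 (-1.20 ± 0.21), KLF10 (-1.19 ± 0.15) and IRF1 (-1.16 ± 0.22). NR4A1 went from 2.95 at 1 h to 0.12 at 4 h (adjusted p = 4.5e-11). Without the 4 h arrays d and e, 9 genes were lower and 1 higher at 4 h, including 7 of the 8, and the difference for DUSP1 was -1.96. With these arrays turned, 12 were lower and 3 higher, including all 8. Between 4 h and 10 h, limma called 0 genes in each of the 3 settings, with 189 at an unadjusted p under 0.05 as deposited. The methods' t-test called 8 there with the ratio limits (7 higher and 1 lower at 10 h, or 22 and 6 if the values are natural logs) and 0 after Benjamini-Hochberg adjustment.

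Between 10 h and 24 h, 3 genes differed. LTBP1, which binds latent TGF-beta in the matrix, was at 0.15 at 10 h and 0.87 at 24 h (difference 0.72 ± 0.11, SE; adjusted p = 0.0054). PKM, the muscle-type pyruvate kinase, was higher at 24 h by 0.89 ± 0.17 (SE; adjusted p = 0.047). NREP, a neuronal regeneration-related gene, was at 0.42 at 10 h and -0.99 at 24 h (difference -1.40 ± 0.19, SE; adjusted p = 0.0013). Without the 4 h arrays d and e, or with these turned, 5 genes differed, including these 3. The 2 time points fitted alone gave 0 genes, and scaling all arrays to an equal spread or quantile normalization gave 0 higher and 1 lower, without LTBP1 and PKM. Leaving out 24 h array a raised the count to 11, and leaving out any other array of the 2 times gave 2.

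Over the whole course, 276 genes passed limma's moderated F test of all time points together, 411 without the 4 h arrays d and e and 478 with these turned. The 276 are fewer than the 382 called at 24 h alone, so they do not count all genes that changed at some time. Calls at 10 h recurred at 24 h. Of the 24 genes that rose at 10 h, 16 also rose at 24 h, where independent lists would share 1.31, and all 5 that fell at 10 h also fell at 24 h, where 0.228 would be shared. No gene called at both times had opposite signs, and the log ratios of the 2 times correlated across genes at r = 0.62. The labels give each time its own starved cells, so no control array is shared, but the times may share RNA batches. All times also share 1 spread per gene in the fit, so the calls at 2 times are not independent. Part of an excess over the count for independent lists may come from this. Of the 17 genes that rose at 1 h, FOSL1 also rose at 24 h, where 0.928 would be shared, and ZFP36L1 fell. Without the 4 h arrays d and e, 7 of 19 genes that rose at 1 h also rose at 24 h, where 1.31 would be shared, and 1 fell. Across genes, the 1 h values correlated with those at 10 h at r = 0.20 and with those at 24 h at r = 0.11.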

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

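Chosen after the result was seen were the tests on the 4 h arrays d and e, the sign patterns of the 4 h arrays (where turning d and e had been tried), and the tests of the unnamed feature for a technical difference and for letters b and d.

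The 8 genes that differed between 1 h and 4 h were all lower at 4 h, by limma contrasts within 1 fit: NR4A1 (-2.83), DUSP1 (-2.55), EGR3 (-2.15), JUNB (-1.87), RHOB (-1.754), NFIL3 (-1.20), KLF10 (-1.19) and IRF1 (-1.16). Of 100 splits of these 9 arrays into groups of the same sizes, 1, the real one, gave as many genes. The highest other split gave 5, against 8. These splits treat arrays as independent, and arrays may share RNA batches, so they argue against chance only on that assumption. Between 10 h and 24 h, LTBP1 was higher at 24 h by 0.72 and PKM by 0.89, and NREP was lower (-1.40). Of 100 splits, 2 gave as many as these 3 genes, a share under 0.05 for this fit that rests on the same assumption and does not exclude chance. The 2 time points fitted alone gave 0 genes, and equal spread on every array and quantile normalization each gave 1 lower and 0 higher, so LTBP1 and PKM lost their calls there. The highest other split gave 12, several times the real count, which points to a structure of the samples: it sets 24 h array a with all 10 h arrays against the other 24 h arrays. Between 4 h and 10 h limma called 0 (189 genes at an unadjusted p under 0.05), and the highest other of 100 splits was 2. A count of 0 is reached by all 100 splits whatever the data, so these splits decide nothing.

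For the tests against 0, the sign patterns of the arrays of a time point are too few for a share under 0.05. The real count at 1 h was 17 genes, reached by 1 of 8 patterns, with 0 in the highest other. At 10 h it was 29, reached by 1 of 8, with 0 in the highest other, and at 24 h 382, reached by 1 of 16, with 122 in the highest other. At 4 h it was 0 (45 at an unadjusted p under 0.05), which all 16 patterns reach whatever the data, and the highest other, 115, is the pattern that turns d and e. For gene lists, the real counts were 3 at 1 h (reached by 4 of 8 patterns, highest other 5), 0 at 4 h (16 of 16, highest other 5), 9 at 10 h (1 of 8, highest other 4) and 9 at 24 h (1 of 16, highest other 7). For the whole course, 276 genes were reached by 1 of 100 drawn sign patterns, the real one, with 272 in the highest other. That other pattern turns 9 arrays, among them 1 h a and d, 4 h a and c, and all 24 h arrays, and a sign turned on all arrays of a time leaves its part of the test as it was. Turning only 4 h arrays d and e, which was not among the patterns drawn, gave 478 genes. The real pattern is thus the highest of those drawn and not of all patterns, so its rank does not exclude chance. The patterns also treat arrays as independent, and arrays may share RNA batches.

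At 10 h, 3 named genes had 1 array far from the rest. CSRP2 was at -0.92 on array e and between -0.40 and -0.37 on the others. LINC02249 was at -0.81 on array e and between -0.65 and -0.63 on the others. MTHFD2 was at 0.19 on array a and between 0.47 and 0.51 on the others. In all, 92 groups of arrays were checked in this way, and chance gives about 1 in 20.

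Features without a single gene symbol, which the gene tests leave out, also changed. Tested feature by feature, 291 of 3965 such features were called at 24 h, 151 rising and 140 falling, and 12 were called at 1 h and 22 at 10 h. At 24 h, 2 of them rose by 2.32 ± 1.34 and 1.71 ± 0.65, and 2 fell (-1.97 ± 0.39 and -1.57 ± 0.39; SD, n = 5 each). The tables used here do not pair these features with a single gene.

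Over the 151 genes called from the 24 h arrays alone, 4 h arrays d and e ran against 4 h arrays a, b and c. They also ran against all 10 h and 24 h arrays there. Over all features, d and e correlated with each other at -0.016. Noise that is independent between genes needs a correlation near 0 with the 24 h response over those 151 genes. The bootstrap 95% interval of r ended at -0.51 for d and lower, at -0.54, for e, which argues against such noise. The bootstrap resampled genes, which are not independent, so its interval does not measure the spread between arrays. It therefore cannot exclude a failed hybridization whose fault is shared by many genes. Also open is that PDGF and starved RNA were exchanged, or the sign of the ratio turned, on both arrays. The slopes of d and e on the 24 h mean were -1.23 and -1.18 times that of a, b and c, which is what a full exchange would give. The same mistake with the dye turn on both arrays stays open too. An unnamed feature that splits the arrays by sign was 5.54 higher on d (2.37) than on e (-3.16), with an SD within a side of at most 0.71. That would speak against it if the feature marks the dye, but the labels give no array's dye to test this. Nothing in the labels decides between these, and no biological explanation was tested, because the design gives no group that sets d and e apart.

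A feature with no gene symbol, singled out after its values were seen, lay between 1.13 and 2.76 on 6 arrays (1 h c and d, 4 h d, 10 h a, 24 h c and e) and between -4.58 and -2.28 on the other 12. A dye swap on letters b and d is argued against as the source of this split, since 9 of 18 arrays follow those letters. A stronger or weaker response to PDGF-BB on 1 side is not decided. The gene-by-gene difference between the sides correlated with the response of the same time point at -0.092, -0.028 and 0.26 for 1, 10 and 24 h. Such a correlation also depends on how noisy the mean of each side is, and array a alone forms a side at 10 h. Dye orientation, or another technical difference that does not depend on the time, remains a candidate explanation: the difference between the sides at 1 h correlated across genes with that at 24 h at r = 0.63. No biological explanation was tested, as the design names no group that divides the arrays in this way.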

How the results depend on the processing

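The settings on 4 h arrays d and e, on 24 h arrays c and e, on natural logs and on the dye term from an unnamed feature were chosen after seeing the data. Of 1232 values of 88 pairs of a named gene and a time under 14 settings, 1011 kept direction and call, 204 kept direction and lost the call, and 17 reversed. All 17 came from turning arrays b and d, which left 0 of the 88 called and moves any response alike on all arrays toward 0 by construction. The list calls kept their camera direction in all 63 combinations with the 3 scalings and lost 6 calls. Filters on missing values and on log ratios beyond 5 were not run, because no cell is missing and none is that large. Signal over background is unknown, so what it limits cannot be given.

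Genes changed at 1, 10 and 24 h numbered 17, 29 and 382, and 276 passed the F test of the whole course, given below as at any time. Centring each array changed no count by over 1.5 times. Equal spread on every array gave 44 genes at 10 h, 134 at 24 h, 153 at any time and 1 between 10 h and 24 h. In place of 2 higher and 1 lower between 10 h and 24 h, it and quantile normalization each called 0 higher and 1 lower. Quantile normalization gave 59, 145 and 159, with 2 between 4 h and 10 h, 1 between 10 h and 24 h, and 6 lists at 1 h. Single features, which are more tests, gave 35 at 1 h, 50 at 10 h, 802 at 24 h, 494 at any time, 18 between 1 h and 4 h and 8 between 10 h and 24 h. Array quality weights, which are lowest for 24 h arrays c and e and also below 1 for 4 h arrays d and e, gave 31, 351, 778 and 770, differences of 13, 2 and 21, and 5 lists at 4 h. Each time point alone gave 219 at 10 h and 151 at 24 h, and the 2 last times alone 0 differences.

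An adjusted p under 0.01 gave 11, 9, 199 and 130. The authors' ratio limits with the adjusted p gave 8 at 10 h and 58 at 24 h, or 143 at 24 h with natural logs. The methods' t-test with the ratio limits gave 11 at 1 h, 14 at 10 h, 56 at 24 h, 8 between 4 h and 10 h and 9 between 10 h and 24 h. If the values are natural logs, it gave 19 rises and 0 falls at 1 h, 41 and 12 at 10 h and 76 and 58 at 24 h. It then gave 1 higher and 21 lower at 4 h than at 1 h (11 in base 2), 22 and 6 at 10 h than at 4 h, and 17 and 20 at 24 h than at 10 h. After Benjamini-Hochberg it gave 2, 0 and 0, and differences of 2 between 1 h and 4 h and 0 between 10 h and 24 h. Camera with an estimated correlation gave 0 lists at 10 h and 1 at 24 h, and fry 5 at 10 h. Stricter thresholds explain the lower counts by construction. For the other settings the cause was not tested, except that turning arrays b and d lowers counts by construction.

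Without 4 h arrays d and e there were 23 genes and 5 lists at 4 h, 135 genes at 10 h and 5 between 10 h and 24 h. With their sign turned there were 115 genes and 5 lists at 4 h, 165 genes at 10 h, 478 at any time, 15 between 1 h and 4 h and 5 between 10 h and 24 h. Without 24 h arrays c and e there were 62 at 10 h. The dye term from the unnamed feature gave 2 genes between 4 h and 10 h and 5 between 10 h and 24 h, and 552 at 24 h.

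The replicate letter as a block gave 11 genes at 10 h and 1 between 4 h and 10 h. The letters showed no clear pairing of the arrays. Same-letter residuals correlated at -0.49 to 0.51 (median -0.03), 9 of 24 pairs over 0.1. Different-letter residuals correlated at -0.58 to 0.52 (median -0.01), 33 of 97 pairs over 0.1. Of 18 arrays, 7 correlated best with their own letter. The share that chance would give was not computed, so some pairing cannot be excluded.

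Turning arrays b and d gave 0 genes at 1, 10 and 24 h, at any time, between 1 h and 4 h and between 10 h and 24 h, and 0, 2 and 3 lists at 1, 10 and 24 h. It reversed DUSP4 (-0.21), DUSP5 (-0.030), EGR3 (-0.19) and NR4A1 (-0.019) at 1 h. At 24 h it reversed ACSL4 (-0.16), ALDOA (-0.00036), AURKA (-0.11), DUSP6 (-0.019), FBLN2 (0.15), FGF7 (0.18), HBEGF (-0.10), IFIT1 (0.043), INSIG1 (-0.072), MT1X (-0.25), TIMP1 (-0.018), VEGFC (-0.020) and ZFP36L1 (0.032). None was past the threshold there. Within a time point the turned arrays offset the others, so a response alike on all arrays moves toward 0 by construction. The lost calls and reversed signs therefore say nothing about how stable these genes are.

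Leaving out 1 array at a time gave 11 to 13 genes at 1 h, 0 at 4 h, 2 to 16 at 10 h, 233 to 430 at 24 h and 163 to 348 at any time. Differences ranged from 7 to 9 between 1 h and 4 h, 0 to 2 between 4 h and 10 h and 2 to 11 between 10 h and 24 h. Counts moved by over 1.5 times without 1 h array a or c (11 each), without any of the 10 h arrays (16, 5, 2 and 5 for a, b, c and e), without 24 h array b (233 at 24 h) and, at any time, without 24 h array b or d (163 and 179). The differences moved without 24 h array a (11 between 10 h and 24 h) and without 4 h array a or 10 h array b (1 and 2 between 4 h and 10 h). Lists ranged from 2 to 5 at 1 h (5 without array b), 0 to 4 at 4 h (4 without d or e), 6 to 8 at 10 h and 8 to 11 at 24 h. Of the named genes, 7 of 11 at 1 h, 0 of 14 at 10 h and 43 of 63 at 24 h kept their call throughout, none reversed, and DUSP5 at 1 h and CSRP2, HMGCS1, LINC02249, SRSF3 and TUBA8 at 10 h lost it with each array.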

Other observations

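The test of early genes below was chosen after 24 h values of some of them had been seen.

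Several genes outside the lists that the report leads with also moved at 24 h. The metallothionein gene MT1X rose by 0.99 ± 0.53 and NQO1, a quinone reductase of the oxidative stress response, by 0.55 ± 0.13 (SD, n = 5 each), 2 of 6 genes of the heat shock and oxidative stress list, which did not pass camera (adjusted p = 0.11). Metallothioneins are near-identical, so the family member is uncertain. The chaperone gene HYOU1 rose by 0.77 ± 0.42, SDF2L1 by 0.60 ± 0.35 and CANX by 0.35 ± 0.15 (SD, n = 5 each), 3 of 7 endoplasmic reticulum chaperones (adjusted p = 0.13). WARS1 rose by 0.54 ± 0.34 (SD, n = 5) in the amino acid list (adjusted p = 0.061). CYCS, cytochrome c, rose by 0.98 ± 0.44, while COX4I1 fell (-0.24 ± 0.14; SD, n = 5 each) in the respiratory chain list (adjusted p = 0.33). IFIT1 (-0.81 ± 0.34) and IFITM1 (-0.38 ± 0.31; SD, n = 5 each) fell in the interferon list (adjusted p = 0.24).

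Secreted growth factors went both ways at 24 h. VEGFC (0.61 ± 0.27) and HBEGF (0.74 ± 0.36) rose, while the chemokine gene CXCL12 (-0.49 ± 0.32) and FGF7 (-0.47 ± 0.57) fell (SD, n = 5 each), and the list did not pass camera (adjusted p = 0.77). FGF7 was below 0 on 4 of 5 arrays. DUSP6, a feedback phosphatase for ERK, rose by 1.02 ± 0.53 (SD, n = 5), the 1 of 11 feedback genes called (list adjusted p = 0.061). Without the 4 h arrays d and e, 4 were called: DUSP6, DUSP5 (0.73 ± 0.25), RGS2 (0.45 ± 0.15) and SPRY2 (0.41 ± 0.31; SD, n = 5 each). The list then passed (adjusted p = 0.0072) and did not with an estimated correlation (adjusted p = 0.066). Among immediate-early genes, ID2 (-0.85 ± 0.32) and ZFP36L1 (-0.43 ± 0.15) fell and FOSL1 rose by 0.37 ± 0.27 (SD, n = 5 each), and NR4A3 was called lower (-0.43 ± 0.15) although its 2 features disagree in sign (-0.95 and 0.08). This list did not pass (adjusted p = 0.60).

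Over the 151 genes called from the 24 h arrays alone, the slope of an array's log ratios on the 24 h mean averaged 0.058 at 1 h, 0.50 at 10 h (0.42 to 0.68) and 1 at 24 h by construction. At 4 h it averaged 0.032 over all arrays as deposited (-0.33 to 0.38), lower than at 1 h, and 0.27 on arrays a, b and c, which were set apart after seeing the data. Because the genes were picked at 24 h, their 24 h values are inflated, which lowers the other slopes.

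A hypothesis was that the genes that rose at 1 h fall below the starved level late in the response, as ZFP36L1 did. The 17 genes argue against it. At 24 h, 14 had a mean above 0 and 3 below, with a median of 0.18, and camera with an estimated correlation did not find them lower than other genes (p = 0.20, in the direction of higher). With the preset correlation used for the gene lists, they stood above other genes (p = 0.026 at 24 h and p = 0.0025 at 10 h). Of these genes, 1 was called higher and 1 lower at 24 h, and without the 4 h arrays d and e, 7 of 19 genes that rose at 1 h were called higher and 1 lower. At 10 h, 15 of 17 had a mean above 0, with a median of 0.20 (p = 0.092 with an estimated correlation). After Benjamini-Hochberg adjustment over the later time points, camera gave an adjusted p of 0.31 at 24 h and 0.27 at 10 h.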
